A study of Mus musculus with 24 samples.

How the data were processed

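RNA of 24 samples of embryonic mouse diaphragm (C57BL/6J), 8 each of pleuroperitoneal fold at E11.5 and E12.5 and of diaphragm at E16.5, was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample. Per the labels, tissue was cut by laser capture (Arcturus XT) from cryosections, RNA was isolated with PicoPure columns and DNase, and cDNA was amplified with NuGEN WT-Ovation Pico and labelled with the Encore Biotin kit. Arrays were grouped by stage as the labels give it. The labels also carry replicate numbers, 1 to 8 in each stage, and do not say that equal numbers belong together or which embryo a sample came from.

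The values deposited by the authors are log2 intensities from RMA, 1 per probe set and array. RMA corrects for background, brings the arrays to a common distribution by quantile normalization and summarises probes by median polish. Affymetrix Expression Console 1.1, RMA and R 2.9.2 are the tools named, without their roles, and whether the 24 arrays were normalized together is not stated. The scale is not named either: log2 was read from the range of the values, 2.56 to 14.1, with array medians of 7.44 to 7.55. There were 0 missing values. Arrays have no read depth, so the number of arrays sets the precision.

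Of 24200 probe sets, 20760 matched 1 gene symbol. The 1140 with several symbols and the 2300 without a gene were left out, since their values belong to no single gene. For the 804 genes with several probe sets the one with the highest mean log2 value was kept, which gave 19351 genes. No gene was removed for a low value; after the data were seen, the arrays in which a named gene lay below the array's lower quartile over genes, or among its 20 brightest, were counted.

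The choices below were made before the data were examined, unless another time is stated. Each pair of stages was compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per stage, all 24 arrays, no covariates), with p-values adjusted by Benjamini and Hochberg over all genes and a threshold of 0.05. Tests were two-sided. A change of 2-fold or more was counted apart. Genes changed at both steps were classed by direction, and the number expected of independent lists is the product of the counts divided by the genes tested. Principal components and Pearson correlations between arrays used all genes. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

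Gene lists numbered 27, with 717 entries, of which 41 had no match among the genes. They cover diaphragm hernia genes, sarcomere proteins, myogenic regulators, calcium handling with excitation-contraction coupling, the neuromuscular junction, muscle energy metabolism, oxidative phosphorylation, cell cycle, extracellular matrix, tendon, muscle connective tissue and fold mesenchyme, mesothelium, the retinoic acid, Hedgehog and Wnt pathways, Hox genes and imprinted growth genes. Markers of neurons, Schwann cells, endothelium, macrophages, erythroid cells, hepatocytes, lung epithelium, cardiomyocytes, and cartilage and bone, and immediate early and heat shock genes complete them. All were written from general knowledge, none from these arrays. Each list was tested in each comparison with camera at a preset correlation of 0.01 between genes, adjusted over all 81 tests, and again with the correlation estimated from the data and with fry, which asks whether a list's genes move on balance in 1 direction.

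Genes were named by a fixed rule: in each comparison the 8 largest rises and 8 largest falls among changed genes whose stages did not overlap, leaving out unnamed gene models, olfactory and vomeronasal receptors and small RNAs. Further, up to 4 changed members of each list with the largest change, any member of the hernia, myogenic and retinoic acid lists, up to 6 genes in each class of the pattern over both steps, and the sex-linked markers. The text names a part of the genes that this rule gives. Tpm3 and the genes of the families described at the end were singled out after their values had been seen.

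Alternatives to these choices were a fit of only the stages compared, replicate number as a block, quantile normalization of the values again, centring arrays on the median or on the 75th percentile, leaving out the dimmest 25% or 50% of genes, and the mean over a gene's probe sets. Others were eBayes with trend and robust options, array weights, an unmoderated unequal-variance test, limma's treat against a fold of 1.5, components from the 1000 most variable genes, and leaving out each array in turn. The hepatocyte list's mean per array as a covariate, leaving out E12.5 replicates 2 and 3 together, and leaving out E16.5 replicates 1 to 4 or 5 to 8, were added after the data had been seen. Results were also set against 100 divisions of the arrays into groups of the same sizes, the real one included. Within each stage, an array was singled out when its gap to the nearest array exceeded Dixon's critical value of 0.526 of the range.

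The limma comparison was tested on simulated data with 19351 genes, 200 of them changed. The noise was normal, independent between genes and of 1 SD per gene for all stages. It thus held no outlying arrays, correlated genes or unequal spread, and the rates below may not hold for the real arrays. At a change of 0.5 on the log2 scale 66.7% were recovered for E12.5 with E11.5 and 69.7% for each of the other comparisons, at a change of 1 between 91.0% and 95.5%, and 6 to 11 unchanged genes were called.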

Results

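RNA was measured on Affymetrix Mouse Gene 1.0 ST arrays from diaphragm tissue of C57BL/6J mouse embryos, cut out of cryosections by laser capture. The earlier stages, E11.5 and E12.5, are pleuroperitoneal folds, the paired ridges from which the diaphragm forms. E16.5 is the diaphragm once muscle has filled it, although the array titles keep the fold's name at all 3 stages. Each stage has 8 arrays, 24 in all, and n = 8 arrays per stage holds for every mean and test unless another number is given. Sections were transverse at E11.5 and E12.5 and sagittal at E16.5. After 1 probe set was kept per gene, 19351 genes were compared, and the median log2 value of an array lay between 7.44 and 7.55. The number of arrays limits the precision. The lower quartile of an array lay between 6.40 and 6.64, and below it signal is not told from background here. Where over 4 of the 8 arrays of a gene's lower stage lay below their own lower quartile, its change is a lower bound at best, and such genes are listed in each comparison. The spread narrows at the top of the scale: at E11.5 the median SD between arrays was 0.32 over genes with a mean of 9 to 10 and 0.06 over those at 13 or more. A change is also taken as a lower bound at best where over 4 of the 8 arrays of the higher stage had the gene among their 20 brightest. Each gene is named by its symbol; errors of changes are standard errors and errors of means are SD.

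The arrays were ordered by stage along the main axis of variation. The first principal component held 48.3% of the variance and the second 6.38%. Scores on the first component ran from -36.5 to -29.6 at E11.5, from -25.7 to -7.58 at E12.5 and from 39.1 to 63.9 at E16.5, with no overlap between stages. The mean correlation between arrays was 0.965 within E11.5, 0.975 within E12.5 and 0.973 within E16.5. Between stages it was 0.967 for E11.5 with E12.5, 0.930 for E12.5 with E16.5 and 0.909 for E11.5 with E16.5. E12.5 replicate 2 stood apart on the second component, at -45.4.

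The E16.5 arrays fell into 2 sets of 4 that the labels do not explain. Replicates 1 to 4 had first-component scores of 58.9 to 63.9 and replicates 5 to 8 of 39.1 to 50.5. In a limma comparison made after the data were seen, 626 genes differed between these sets, against at most 1 in the other 34 of 35 divisions of the stage into 4 and 4. At E11.5 and E12.5 the same division by number gave 0 genes each (unadjusted, 738 and 778). These sets did not overlap in the means of 10 of 27 lists, against at most 3 in the other divisions of E16.5. Chance gives 2.86% for a list when the division is fixed beforehand. This division was chosen from the same arrays and the lists are not independent, so that rate does not apply to it. Replicates 1 to 4 were higher for muscle energy metabolism (by 0.70 on the log2 scale), endothelium (0.57), calcium handling (0.52), sarcomere (0.44), oxidative phosphorylation (0.43), immediate early and heat shock genes (0.26), extracellular matrix (0.11) and Wnt (0.08). They were lower for red blood cells (-0.75) and cell cycle (-0.38). Sex differed in part between the sets: Y-linked Eif2s3y lay at 9.08 to 9.99 in replicates 1 to 3 and at 4.15 to 4.54 in replicates 4 to 8. It was also low (at most 4.78) in E11.5 replicates 2 and 3 and in E12.5 replicates 1, 6, 7 and 8. The balance of sexes thus differs between stages, and the fit has no term for sex.

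**Figure D1:**
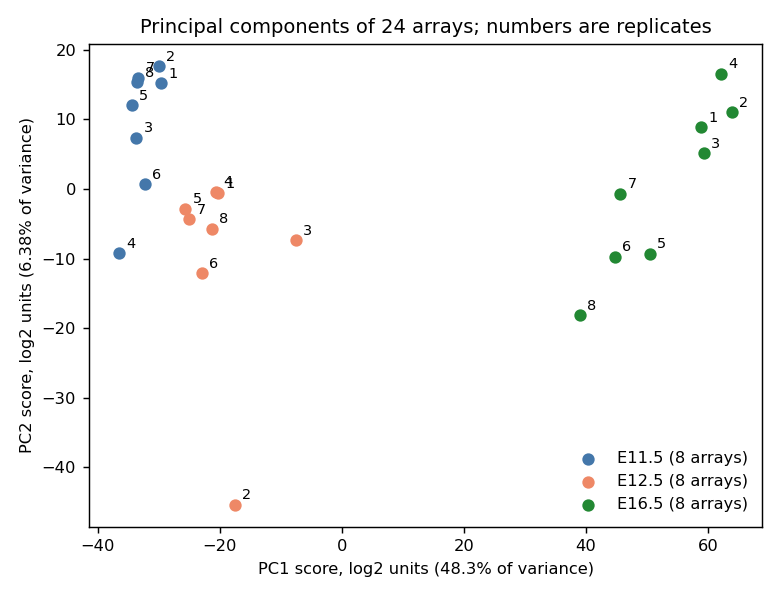
First (48.3% of variance) against second (6.38%) principal component scores of the 24 arrays over 19351 genes, each point 1 array marked by its stage and replicate number. The E16.5 arrays lie between 39.1 and 63.9 on the first component, apart from both earlier stages, and E12.5 replicate 2 lies at -45.4 on the second.

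The comparison of E12.5 with E11.5 asks what changes in the folds in the course of 1 day. Contractile genes of striated muscle rose. Actn2, the Z-disc crosslinker alpha-actinin 2, rose from a mean log2 value of 7.46 ± 0.61 (SD, n = 8) to 9.58 ± 1.19, and Mylpf, a regulatory light chain of fast muscle myosin, from 9.31 ± 0.96 to 11.19 ± 0.85. Transcripts typical of liver rose more, with Alb, which encodes serum albumin, going from 6.15 ± 0.28 to 10.44 ± 1.58. Few genes fell past the threshold, with Nr2f1 first among those named, a nuclear receptor of the COUP-TF family, from 8.67 ± 0.27 to 7.65 ± 0.44. In the limma fit 75 genes changed, 64 higher and 11 lower, and 32 of the higher and 2 of the lower ones moved by 2-fold or more. At an unadjusted p under 0.05 there were 2789 genes, of which 1575 were lower. Among changed genes whose arrays did not overlap between the stages (18 genes, where chance gives 0.0155% of all genes), the 8 largest rises were in Alb, Serpina6, Afp, Apoa2, Ambp, Apoa1, Rbp4 and Smpx, and the falls of named genes were in Nr2f1, Chd6 and Marf1. Calls ended without any 1 of 2 arrays for Ambp (adjusted p up to 0.0547), 7 for Marf1 (0.0764) and 13 for Chd6 (0.0950). Frmpd3 passed too (-0.26), but all its arrays at both stages lay below their lower quartile, so no change of its transcript is shown, and the call ended without any 1 of 12 arrays (0.0933). The changes of Serpina6 and Smpx (8 of 8 E11.5 arrays below their lower quartile), Alb (7), Aspn and Cyp7b1 (6), and Afp and Myoz2 (5) are lower bounds at best.

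Of 44 measured sarcomere genes, 14 rose, 0 fell and 30 were not past the threshold (unadjusted, 30 higher and 0 lower), and 29 rose when adjusted over the list alone. Besides Actn2 (log2 change 2.12 ± 0.37, adjusted p = 0.00931) and Mylpf (1.89 ± 0.35), these included Myl4, the embryonic and atrial myosin light chain (2.0 ± 0.35), and Smpx, a small protein of striated muscle (1.85 ± 0.34). The list as a whole had a median log2 change of 0.83 and was higher in limma's camera test (adjusted p = 5.72e-33), also with a correlation estimated from the data (adjusted p = 0.0352). Among 30 myogenic regulators 2 rose and 0 fell (unadjusted, 9 higher and 2 lower), and adjusted over the list alone 8 were higher and 2 lower. The pair were Mef2c, a muscle transcription factor (1.15 ± 0.17, adjusted p = 0.00180), and Myod1, a determination factor of skeletal muscle (0.74 ± 0.16, adjusted p = 0.0370). Myog, which drives muscle differentiation, had 0.59 ± 0.14 (adjusted p = 0.0682), and the progenitor factors Pax3 and Pax7 had -0.20 ± 0.19 and 0.27 ± 0.10, none of them past the threshold. Myog passed without E11.5 replicate 2 (adjusted p = 0.0456) or 8 (0.0481) or E12.5 replicate 2 (0.00793). As a set the regulators were higher (median 0.02, adjusted p = 0.00138; adjusted p = 0.172 with an estimated correlation), although the median was -0.02 after quantile normalization and -0.01 and -0.06 after centring arrays on the median and the 75th percentile. Without single arrays it ran from -0.004 (E12.5 replicate 1) to 0.09 (E11.5 replicate 2). With fry the list did not pass (adjusted p = 0.0719). Myod1 lost its call when any 1 of 11 arrays was left out (adjusted p up to 0.0781).

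Genes of calcium handling, of the neuromuscular junction, of muscle energy metabolism and of oxidative phosphorylation were higher as sets in camera, mostly without single genes past the threshold. None of these lists passed with fry (adjusted p = 0.107, 0.198, 0.097 and 0.0881 in that order). In calcium handling 1 of 22 genes rose and 0 fell (unadjusted, 8 and 0; 7 higher adjusted over the list alone), with a median log2 change of 0.17 and adjusted p = 1.00e-05, and adjusted p = 0.210 with an estimated correlation. That gene was Hrc, a calcium-binding protein of the sarcoplasmic reticulum (1.54 ± 0.35), whose call ended without any 1 of 22 arrays (adjusted p up to 0.102). At the neuromuscular junction 1 of 15 rose and 0 fell (unadjusted, 4 and 1; 1 higher adjusted over the list alone; median 0.20, adjusted p = 0.00694, and adjusted p = 0.304 with an estimated correlation). It was Musk, the receptor kinase that organises the synapse (0.92 ± 0.21), whose call ended without any 1 of 16 arrays (adjusted p up to 0.0933). Muscle energy metabolism had 0 of 22 genes past limma's threshold, also when adjusted over the list alone, against 6 higher unadjusted (median 0.29, adjusted p = 1.13e-06, and adjusted p = 0.176 with an estimated correlation). Oxidative phosphorylation had 0 of 39 in both counts, against 7 higher unadjusted (median 0.14, adjusted p = 4.62e-09, and adjusted p = 0.210 with an estimated correlation). E12.5 replicate 3 stood apart: without it the medians were 0.08 for calcium handling (0.30 without E12.5 replicate 2), 0.10 for the junction and 0.18 for energy metabolism, with adjusted p of 0.000570, 0.0300 and 0.000309. Centring on the 75th percentile gave 0.09 for calcium handling, 0.13 for the junction and 0.07 for oxidative phosphorylation, the last 0.09 after quantile normalization.

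Liver transcripts rose between E11.5 and E12.5. Of 19 hepatocyte markers 6 rose and 0 fell (unadjusted, 13 and 0), and 11 rose when adjusted over the list alone (median log2 change 1.31, adjusted p = 1.28e-20, and adjusted p = 0.0687 with an estimated correlation). Alb rose by 4.29 ± 0.46 (adjusted p = 3.09e-05, a lower bound at best, as for Afp and Serpina6), Afp, the fetal serum protein alpha-fetoprotein, by 3.53 ± 0.44, and Apoa2, an apolipoprotein, by 3.19 ± 0.45. Serpina6, the corticosteroid-binding globulin, rose by 3.81 ± 0.49 and is not on the list. The spread at E12.5 was wide: the list's mean per array was 11.43 in replicate 2, 9.30 in replicate 4 and 7.43 to 8.19 in the other arrays of that stage, against 6.68 to 6.92 at E11.5. Muscle lists and the liver list rose over the same interval. Of the other tissues' markers, lung epithelium (0 of 19 genes past limma's threshold, 2 lower unadjusted, median -0.06, adjusted p = 0.242), cardiomyocytes (0 of 13, 1 higher and 2 lower unadjusted, median 0.01, adjusted p = 0.767) and cartilage and bone (0 of 18, 2 lower unadjusted, median -0.06, adjusted p = 0.351) did not pass. Nor did neurons (0 of 18, 1 higher and 4 lower unadjusted, median -0.08, adjusted p = 0.101), endothelium (0 of 21, 0 unadjusted, median -0.06, adjusted p = 0.419) or red blood cells (0 of 13, 1 higher and 1 lower unadjusted, median 0.15, adjusted p = 0.148). The neuronal list passed, lower, without E11.5 replicate 4 (adjusted p = 0.0403), and the red blood cell list, higher, without E12.5 replicate 1 (0.0416) or 3 (0.0293). Macrophages (0 of 21, 1 higher and 2 lower unadjusted, adjusted p = 0.816) had a median of -0.03 and a mean of -0.01 while the test pointed up, and Schwann cells (0 of 11, 1 higher and 1 lower unadjusted, adjusted p = 0.715) a median of -0.03 and a mean of 0.08.

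In the fold's own tissue the first interval brought few changes to single genes. The mesenchyme list, transcription factors and signals of muscle connective tissue and fold, had 0 of 29 genes past limma's threshold, with 2 higher and 10 lower unadjusted, and 1 higher and 4 lower adjusted over the list alone. It was lower as a set (median log2 change -0.19, adjusted p = 0.0442, and adjusted p = 0.172 with an estimated correlation). That call ended without E11.5 replicate 3 (adjusted p = 0.0622), 4 (0.277) or 6 (0.119) and without E12.5 replicate 2 (0.121), 4 (0.111), 7 (0.0547) or 8 (0.0541). Hox genes were lower (0 of 28 past limma's threshold and 0 adjusted over the list alone, 10 lower unadjusted; median -0.19, adjusted p = 3.75e-05, and adjusted p = 0.0643 with an estimated correlation). Extracellular matrix genes were higher (0 of 41, 12 higher and 1 lower unadjusted, 5 higher adjusted over the list alone; median 0.10, adjusted p = 5.69e-06, and adjusted p = 0.172 with an estimated correlation). So were imprinted growth genes (0 of 18, 6 higher and 1 lower unadjusted, 3 higher adjusted over the list alone; median 0.12, adjusted p = 0.000884, and adjusted p = 0.128 with an estimated correlation). Scaling moved both medians: for matrix genes to 0.05 after quantile normalization and 0.03 with 75th-percentile centring, and for imprinted genes to 0.08 and 0.04. Without E11.5 replicate 7 the matrix median was 0.07. With fry the matrix list did not pass (adjusted p = 0.0881). Aspn, a small leucine-rich matrix proteoglycan on the tendon list, rose by 2.0 ± 0.35, the 1 of 15 tendon genes to do so (median 0.04, adjusted p = 0.206 for the list).

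Genes linked to diaphragmatic hernia in mice or people did not move in 1 direction as a set at this step. Of 41, 1 rose (Myod1) and 0 fell (unadjusted, 6 higher and 1 lower), 4 were higher and 1 lower adjusted over the list alone, and the median was -0.04, with a mean of 0.02 and the test pointing up (adjusted p = 0.245). In fry's mixed form, which counts changes either way, the hernia list passed (adjusted p = 1.22e-05). So did the retinoic acid (2.5e-14) and Wnt (1.14e-05) lists. Of 24 retinoic acid genes, Rbp4, the plasma carrier of retinol, rose (2.22 ± 0.42) and Nr2f1 fell (-1.01 ± 0.16, adjusted p = 0.00354), with 3 higher and 2 lower adjusted over the list alone (median 0.05, adjusted p = 0.194). Rbp4 and Ttr, the carrier it travels with in blood, are 2 genes that the retinoic acid and hepatocyte lists share. Aldh1a2, the main enzyme of retinoic acid synthesis in the embryo, had -0.67 ± 0.35 (adjusted p = 0.386), and -0.31 without E12.5 replicate 4, which lay at 7.62 against 10.16 or more in the other arrays of that stage. Of 43 Wnt genes Rspo3, which amplifies Wnt signals, rose (1.58 ± 0.24, adjusted p = 0.00282) and 0 fell (unadjusted, 4 higher and 2 lower; median -0.05, mean 0.00, adjusted p = 0.951). Neither Hedgehog genes (0 of 17 past limma's threshold, 2 lower unadjusted, median 0.00, adjusted p = 0.802) nor mesothelium (0 of 18, 2 lower unadjusted, median -0.11, adjusted p = 0.169) passed. Cell cycle genes (0 of 52, 2 higher unadjusted, median 0.03, adjusted p = 0.0844) did not either. The cell cycle list passed, higher, without E11.5 replicate 3 (adjusted p = 0.0305), 4 (0.0187) or 6 (0.0479) or E12.5 replicate 1 (0.0402) or 4 (0.0406), and mesothelium, lower, without E11.5 replicate 7 (0.0314). Immediate early and heat shock genes had 1 of 22 higher, the growth regulator Myc (0.62 ± 0.13, adjusted p up to 0.0600 without any 1 of 4 arrays), with a median of -0.04, a mean of 0.04 and adjusted p = 0.564.

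The count of 75 genes depends on single arrays and on the fit. It was 137 without E11.5 replicate 4, 43, 38 and 42 without E11.5 replicates 5, 7 and 8, and 26, 151, 31, 33, 36 and 33 without E12.5 replicates 1, 2, 3, 4, 6 and 8. It was 9 with the other stage left out of the fit, and 0 in an unmoderated unequal-variance test with 2502 genes past it unadjusted. The main fit takes 1 spread per gene over all 3 stages. Actn2, for one, had an SD of 0.61 at E11.5, 1.19 at E12.5 and 0.24 at E16.5. For such genes the standard errors given at this step are too small. With arrays centred on their 75th percentile 51.6% of the changed genes were higher, against 85.3% here, and of 28 changed genes named at this step 14 kept their call with each array left out.

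The comparison of E16.5 with E12.5 asks how the muscularised diaphragm differs from the folds. Nearly all genes of the sarcomere, of calcium handling and of muscle energy metabolism rose, genes of fold mesenchyme and of cell division fell, and genes linked to diaphragmatic hernia were lower for the most part. Atp1b4, a muscle protein related to the sodium pump's beta subunit, rose from a mean log2 value of 6.63 ± 1.65 (SD, n = 8) to 12.66 ± 0.15, a change of 6.03, and of 6.61 without E12.5 replicate 3. Crabp2, which carries retinoic acid in the cell, fell 14.8-fold, from 12.15 ± 0.19 to 8.27 ± 0.54. Altogether 5241 genes changed, 2223 higher and 3018 lower, and 702 of the higher and 341 of the lower ones moved by 2-fold or more. For 1941 of the changed genes each array of 1 stage lay above each array of the other, where chance gives 0.0155% of the genes. Of those, the 8 largest rises were in Atp1b4, Dpt, Ppp1r3a, Cox8b, Myl2, Casq1, Cmya5 and Sftpc (log2 changes of 4.80 to 6.03), and the 8 largest falls in the globins Hbb-bh1, Hba-x and Hbb-y and in Fat3, Crabp2, Rimklb, Tmtc2 and Mpped2 (-5.67 to -2.96). Lower bounds at best are the rises of Sftpc (8 of 8 E12.5 arrays below their lower quartile) and of Atp1b4, Ckmt2, Dpt, Myf6 and Ppp1r3a (7 each). So are the falls of Nefm and Rimklb (7 of 8 E16.5 arrays), Hbb-bh1 (6), and Cyp7b1 and Nr2f1 (5). At the top of the scale the same holds for the fall of Hbb-y (8 of 8 E12.5 arrays) and the rise of Mylpf (5 of 8 E16.5 arrays).

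Of 44 sarcomere genes 43 rose and 1 fell, Tpm3, a tropomyosin made in many cell types, with the same numbers adjusted over the list alone. The median log2 change was 2.74 (adjusted p = 7.72e-43). Myl2, the slow and cardiac regulatory light chain, rose by 4.94 ± 0.56 (adjusted p = 1.87e-07), Myh8, the perinatal myosin heavy chain, by 4.31 ± 0.43, and Myl1, a fast light chain, by 4.19 ± 0.33. For genes with a much wider spread at E12.5 than at the other stages, standard errors are too small at this step too. Myl2 had an SD of 0.20 at E11.5, 2.06 at E12.5 and 0.05 at E16.5, and its adjusted p was up to 0.00241 over the alternatives. All 22 genes of calcium handling rose (median 2.41, adjusted p = 4.60e-29), among them Casq1 (4.89 ± 0.37), which stores calcium in the sarcoplasmic reticulum, Trdn (4.51 ± 0.32), which anchors it to the release channel, and the calcium pump Atp2a1 (3.37 ± 0.30). All 22 of muscle energy metabolism rose (median 3.04, adjusted p = 1.49e-32), among them Cox8b (5.10 ± 0.34) and Cox7a1 (4.50 ± 0.29), muscle forms of cytochrome oxidase subunits, and the mitochondrial creatine kinase Ckmt2 (4.47 ± 0.32). All 39 of oxidative phosphorylation rose by less (median 0.70, adjusted p = 4.60e-29), led by Atp5g1 (1.34 ± 0.17, and 0.85 to 1.83 over the alternatives), a subunit of ATP synthase. Those 3 lists had the same counts adjusted over the list alone, and all 4 calls held with an estimated correlation. At the neuromuscular junction 9 of 15 rose and 1 fell, with 13 and 1 adjusted over the list alone (median 0.45, adjusted p = 3.68e-06, and adjusted p = 0.104 with an estimated correlation). The acetylcholine receptor subunits Chrnd (1.45 ± 0.14), Chrng (1.38 ± 0.21) and Chrnb1 (1.16 ± 0.18) were among them.

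Myogenic regulators split. Of 30, 9 rose and 7 fell, with 10 and 7 adjusted over the list alone. Myf6, the regulator of late muscle differentiation, rose by 4.33 ± 0.22 (adjusted p = 2.55e-13), Mymk, which fuses myoblasts, by 1.32 ± 0.22, Mef2c by 1.21 ± 0.17 and Mef2a by 0.92 ± 0.10. Myod1 fell (-0.52 ± 0.16, adjusted p = 0.0143), as did Eya1 (-0.75 ± 0.18) and Meox1 (-0.74 ± 0.18), factors of early muscle progenitors and somites, and Msc (-0.54 ± 0.12), a repressor of the MyoD family. Pax7 fell slightly (-0.27 ± 0.10, adjusted p = 0.0379), a call that ended without any 1 of 9 arrays (adjusted p up to 0.0899). Myog had 0.36 ± 0.14 (adjusted p = 0.0690) and passed without E11.5 replicate 4 (adjusted p = 0.0382) or E12.5 replicate 3 (0.0353). As a set the list was higher (median 0.16, adjusted p = 0.0205; adjusted p = 0.304 with an estimated correlation), a call that ended without E12.5 replicate 2 (adjusted p = 0.0523) and without E16.5 replicates 1 to 4 together (0.0504). Without those 4 arrays Msc had -0.42 (adjusted p = 0.0522), and without E16.5 replicates 5 to 8 Myod1 had -0.45 (0.134). Pax7 lost its call without either set (0.208 and 0.0891).

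**Figure D2:**
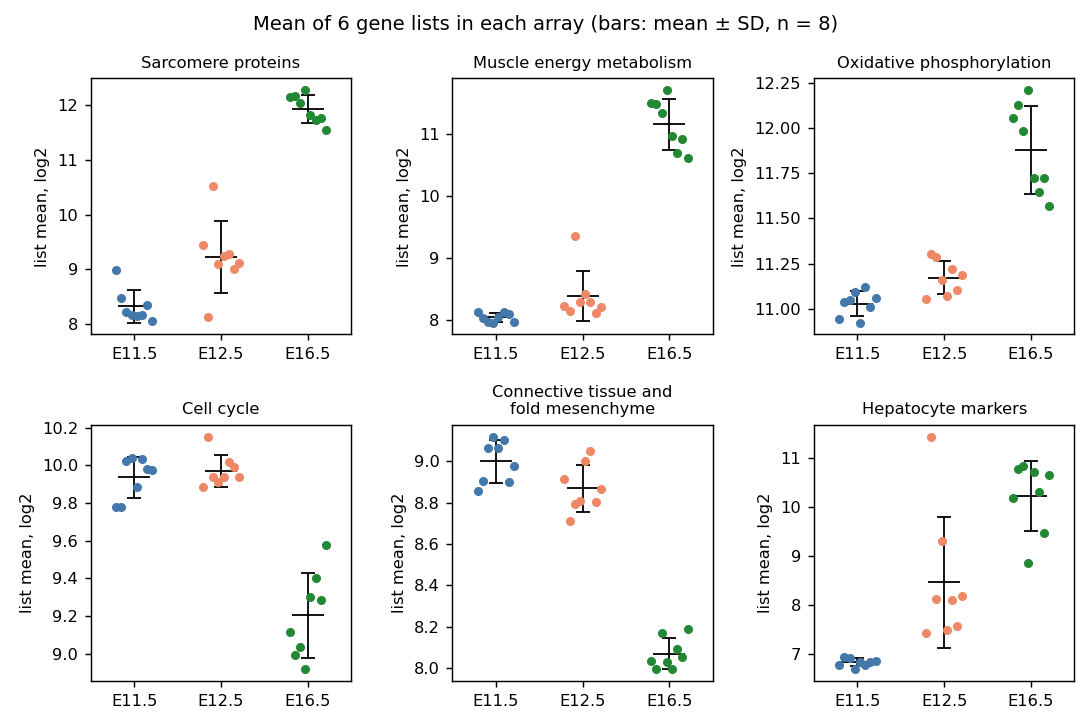
Mean log2 value over the genes of a list, in each of the 24 arrays by stage, for 6 lists (sarcomere proteins, muscle energy metabolism, oxidative phosphorylation, cell cycle, connective tissue and fold mesenchyme, hepatocyte markers); bars are the stage mean ± SD, n = 8. The sarcomere mean goes from 8.32 at E11.5 to 9.23 at E12.5 and 11.94 at E16.5, fold mesenchyme from 9.0 to 8.87 and 8.07, and the hepatocyte mean spreads widely at E12.5 (SD 1.34).

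Cell cycle genes fell: 0 of 52 rose and 48 fell (unadjusted, 0 and 50), and 50 fell adjusted over the list alone (median log2 change -0.75, adjusted p = 3.14e-24, held with an estimated correlation). Ccnd2, a D-type cyclin, fell by 1.48 ± 0.08 on the log2 scale, the spindle checkpoint kinase Bub1 by 1.38 ± 0.18, and Gins1, part of the replicative helicase, by 1.29 ± 0.18.

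Fold mesenchyme fell as well. Of 29 genes 1 rose and 21 fell, with 2 and 21 adjusted over the list alone (median -0.80, adjusted p = 6.85e-10, held with an estimated correlation). Examples are Hgf, the growth factor that draws migrating muscle progenitors (-2.43 ± 0.26), and the transcription factors Twist1 (-1.81 ± 0.14), Tbx5 (-1.71 ± 0.23) and Meis2 (-1.69 ± 0.15). Extracellular matrix genes went mostly up, with 23 of 41 higher and 6 lower, and 24 and 7 adjusted over the list alone (median 0.36, adjusted p = 5.86e-06; adjusted p = 0.172 with an estimated correlation). The fibril-associated collagen Col14a1 rose by 2.31 ± 0.17 and the basement membrane laminin chain of muscle, Lama2, by 1.83 ± 0.12. Dpt, dermatopontin, a matrix protein outside the lists, rose by 5.64 ± 0.47. Of 15 tendon genes 5 rose and 1 fell, with 5 and 2 adjusted over the list alone, among them Aspn (3.55 ± 0.35) and Thbs4, a thrombospondin of tendon and muscle (1.71 ± 0.15; list median 0.12, adjusted p = 0.00755, and adjusted p = 0.0935 with an estimated correlation). Tnmd, the tendon membrane protein tenomodulin, rose by 1.55 ± 0.51, a call that ended without any 1 of 3 arrays (adjusted p up to 0.0557). In 4 of 8 E16.5 arrays it lay within the E12.5 range, at 6.21 to 6.59, and without E16.5 replicates 5 to 8 its change was 0.56 (adjusted p = 0.254).

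Genes linked to diaphragmatic hernia fell more often than they rose: 24 of 41 fell and 5 rose, and adjusted over the list alone 27 and 6 (median -0.54, adjusted p = 1.26e-06, held with an estimated correlation). Besides Hgf, the falls included Robo1, a receptor of Slit guidance signals (-2.35 ± 0.15), Aldh1a2 (-2.12 ± 0.35), the growth factor receptor Pdgfra (-1.59 ± 0.12), the zinc finger factor Wt1 (-1.44 ± 0.13), Gata6 (-1.38 ± 0.17), Gata4 (-0.94 ± 0.14) and their partner Zfpm2 (-0.85 ± 0.18). Mef2a, the membrane receptor Fgfrl1 (0.61 ± 0.12) and elastin, Eln (0.45 ± 0.08), were among the rises. So were Lox, which crosslinks collagen and elastin (0.53 ± 0.17), and the collagen Col3a1 (0.26 ± 0.10), whose calls ended without any 1 of 3 and of 10 arrays (adjusted p up to 0.0602 and 0.0973). Without E16.5 replicates 1 to 4 Fgfrl1 had 0.34 (adjusted p = 0.0621) and Col3a1 0.30 (0.120), and without replicates 5 to 8 Lox had 0.33 (0.270) and Col3a1 0.23 (0.212). Of these 41 genes 8 are also on the mesenchyme list and 7 on the list of myogenic regulators. Retinoic acid genes fell in 12 of 24 cases and rose in 4, with 13 and 4 adjusted over the list alone (median -0.25, adjusted p = 0.000828, held with an estimated correlation). The largest falls were Crabp2 (-3.89 ± 0.18, adjusted p = 8.14e-14), Crabp1 (-2.29 ± 0.29), which binds the same ligand, and Aldh1a2. Ttr rose by 2.56 ± 0.47 and Rbp4 by 1.21 ± 0.42 (adjusted p = 0.0329), the latter a call that ended without any 1 of 9 arrays (adjusted p up to 0.0771) and without E16.5 replicates 5 to 8 together (0.248).

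**Figure D3:**
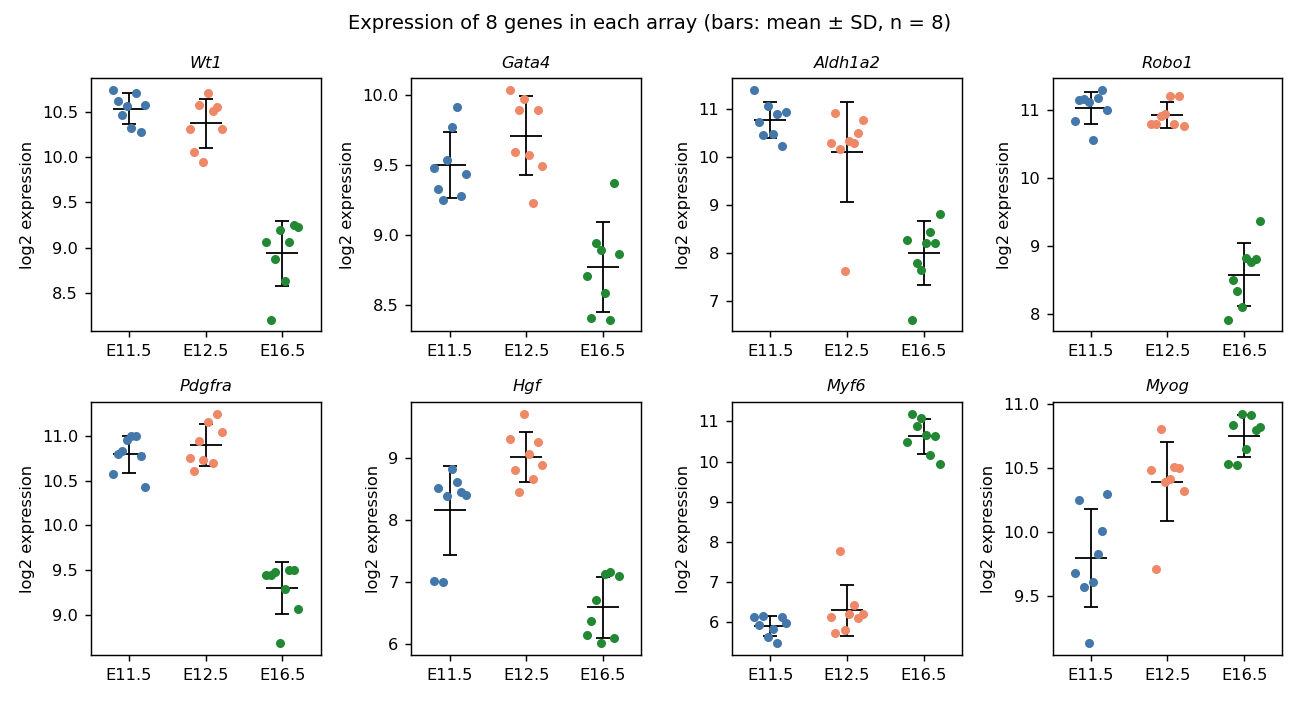
Log2 value of 8 genes in each of the 24 arrays by stage; bars are the stage mean ± SD, n = 8. Wt1, Gata4, Aldh1a2, Robo1, Pdgfra and Hgf are lower at E16.5 than at E12.5, Myf6 goes from a mean of 6.30 at E12.5 to 10.63 at E16.5, and Myog has 10.39 and 10.75.

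Signalling and patterning lists were lower. Of 17 Hedgehog genes 7 fell and 0 rose (unadjusted, 8 and 0; 8 lower adjusted over the list alone), led by the transcription factor Gli3 (-1.47 ± 0.15; list median -0.25, adjusted p = 0.0101, and adjusted p = 0.134 with an estimated correlation). Of 43 Wnt genes 18 fell and 3 rose, with 21 and 3 adjusted over the list alone, including the secreted inhibitors Sfrp1 (-1.97 ± 0.15) and Frzb (2.17 ± 0.35; list median -0.23, adjusted p = 0.00398, and adjusted p = 0.0746 with an estimated correlation). Of 28 Hox genes 14 fell and 0 rose (unadjusted, 15 and 0; 15 lower adjusted over the list alone), among them Hoxa5, which patterns the neck and chest (-1.31 ± 0.17; list median -0.30, adjusted p = 0.000116, and adjusted p = 0.0746 with an estimated correlation). Of 18 imprinted genes 9 rose and 3 fell, with 10 and 4 adjusted over the list alone (median 0.24, adjusted p = 0.0106, and adjusted p = 0.219 with an estimated correlation). The non-coding Meg3 (1.13 ± 0.14) and its neighbour Rtl1 (1.55 ± 0.13) rose and Nnat, neuronatin, fell (-2.30 ± 0.12). Without E16.5 replicates 5 to 8 the Hedgehog (adjusted p = 0.0695), Wnt (0.0537) and imprinted (0.0639) lists did not pass. The change of Frzb kept its call but ran from 1.23 to 3.10 over the alternatives.

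Markers of other cell types moved over the same interval as the muscle genes. Of 19 hepatocyte markers 16 rose and 0 fell, also adjusted over the list alone and unadjusted (median log2 change 1.61, adjusted p = 8.30e-08, and adjusted p = 0.232 with an estimated correlation). The fibrinogen chain Fgg rose by 3.27 ± 0.57, and Alb was at 12.81 ± 0.57 (SD, n = 8) at E16.5, with the list mean at 8.85 to 10.83 per array. Sftpc, the surfactant protein of lung alveolar cells, rose by 4.80 ± 0.48 and ranged from 8.0 to 12.73 over the E16.5 arrays, against 5.59 to 6.14 before; of 19 lung genes 3 rose and 1 fell, also adjusted over the list alone (median 0.10, adjusted p = 0.0808, and 0.0484 without E16.5 replicate 7). Of 13 cardiomyocyte genes 4 rose and 0 fell, also adjusted over the list alone and unadjusted (median 0.17, adjusted p = 0.0267, and adjusted p = 0.241 with an estimated correlation). That call ended without E16.5 replicate 8 (median 0.09, adjusted p = 0.0813), as it did without E16.5 replicates 5 to 8 together (0.0815), while the lung list passed without those (0.0242). Myl2, with the largest change, is also a sarcomere gene. Of 21 endothelial genes 14 rose and 0 fell (unadjusted, 15 and 1; adjusted over the list alone, 14 and 1), among them Pecam1, an adhesion molecule of vessel walls (1.54 ± 0.22; list median 0.42, adjusted p = 2.32e-05, and adjusted p = 0.178 with an estimated correlation). The endothelial mean was 8.61 to 8.86 in E16.5 replicates 1 to 4 and 8.03 to 8.26 in replicates 5 to 8, against 7.80 to 8.13 at E12.5. Without replicates 1 to 4 the list did not pass (median 0.15, adjusted p = 0.0640), and without replicates 5 to 8 it had a median of 0.66 (4.23e-09). Of 21 macrophage genes 4 rose and 0 fell, also adjusted over the list alone (unadjusted, 9 and 0), with lysozyme, Lyz2, at 2.30 ± 0.29 (list median 0.31, adjusted p = 0.00251, and adjusted p = 0.128 with an estimated correlation). Of 18 mesothelial genes 3 rose and 4 fell (median -0.06, adjusted p = 0.707).

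The embryonic globins fell. Hbb-bh1 fell by 5.67 ± 0.29 on the log2 scale (adjusted p = 3.07e-13), a lower bound at best, and Hba-x by 4.80 ± 0.18. Hbb-y fell by 4.21 ± 0.40, a lower bound at best too, and its change was -3.01 in the alternative with the smallest fall. These were the only 3 of 13 red blood cell genes past the threshold, also adjusted over the list alone and unadjusted (list median -0.10, adjusted p = 0.0534). The list passed, lower, without E12.5 replicate 1 (adjusted p = 0.0236), 3 (0.0259), 6 (0.0310) or 7 (0.0473) or E16.5 replicate 5 (0.0338), 6 (0.0284) or 8 (0.0160), or without E16.5 replicates 5 to 8 together (median -0.30, adjusted p = 0.000795). Without replicates 1 to 4 its median was 0.29 (0.322). With fry the list passed (adjusted p = 0.000425). Hbb-y lay between 7.81 and 11.21 in the E16.5 arrays and between 13.46 and 13.71 in the earlier ones. Of 18 neuronal genes 4 fell and 1 rose, among them Nefm, a neurofilament (-1.84 ± 0.27; median -0.01, adjusted p = 0.467), and of 11 Schwann cell genes 1 fell and 0 rose in limma (unadjusted, 2 lower; median -0.03, adjusted p = 0.910). The former was Erbb3, a neuregulin receptor (-0.39 ± 0.14, adjusted p up to 0.0795 without any 1 of 5 arrays, and -0.12 with adjusted p = 0.660 without E16.5 replicates 1 to 4). Of 18 cartilage and bone genes 3 rose and 1 fell, with a median of 0.00, a mean of 0.16 and the test pointing up (adjusted p = 0.635), and Sox9, a cartilage regulator, fell by 0.92 ± 0.11 on the log2 scale. Of 22 immediate early and heat shock genes 8 rose, led by the small heat shock protein Hspb1 (2.54 ± 0.23), and 1 fell, Myc (-1.18 ± 0.13; list median 0.20, adjusted p = 0.000359, and adjusted p = 0.104 with an estimated correlation).

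Stage and plane of section changed together between E12.5 and E16.5. Each value is relative to the rest of a mixed tissue's RNA, so the falls above do not show lower expression per cell. With 75th-percentile centring 50.9% of 5004 changed genes were higher, against 42.4% here, and 3479 genes changed without E16.5 replicates 1 to 4. The labels do not tie captured regions to animals, so arrays of a stage may share an embryo; the p-values measure only the spread between these arrays and are too small where regions share one.

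The comparison of E16.5 with E11.5 spans both intervals. Muscle genes showed their largest changes here: Smpx rose from a mean log2 value of 6.08 ± 0.23 (SD, n = 8) to 12.31 ± 0.19, and Cox8b 53.8-fold. Alb rose from 6.15 ± 0.28 to 12.81 ± 0.57, and the globin Hbb-bh1 fell from 12.92 ± 0.20 to 6.30 ± 0.57. Fold and patterning genes fell, among them Tbx5 (log2 change -2.38 ± 0.23), Meis1, a partner of Hox proteins (-1.95 ± 0.10), and Hoxc5 (-1.61 ± 0.21). In limma 6479 genes changed, 2680 higher and 3799 lower, with 887 of the higher and 377 of the lower ones at 2-fold or more. For 1757 of them the arrays of the stages did not overlap (by chance, 0.0155% of all genes). Of those, the 8 largest rises were in Alb, Atp1b4, Smpx, Myl2, Dpt, Cox8b, Myoz2 and Ppp1r3a (5.72 to 6.65), and the 8 largest falls in Hbb-bh1, Hba-x, Hbb-y, Crabp2, Fat3, Rimklb, Otor and Mpped2 (-6.62 to -3.29). Lower bounds at best are the rises of Atp1b4, Myf6, Ppp1r3a and Smpx (8 of 8 E11.5 arrays below their lower quartile), Alb, Dpt and Myl2 (7) and Myoz2 (5), and the falls of Otor (8 of 8 E16.5 arrays), Rimklb (7), Hbb-bh1 (6) and Nr2f1 (5), and of Hbb-y at the top of the scale (8 of 8 E11.5 arrays). Of the 16 hepatocyte markers that rose 7 are such, and 5 of 44 sarcomere genes.

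The muscle lists rose almost without exception: 43 of 44 sarcomere genes, with Tpm3 lower (median log2 change 3.83, adjusted p = 1.60e-52), and each of the 22 calcium handling (2.62, adjusted p = 2.94e-29), 22 energy metabolism (3.36, adjusted p = 9.60e-33) and 39 oxidative phosphorylation genes (0.85, adjusted p = 5.72e-33). All 4 calls held with an estimated correlation. Of 30 myogenic regulators 12 rose and 6 fell (median 0.25, adjusted p = 0.000638; adjusted p = 0.147 with an estimated correlation). Myf6 rose by 4.72 ± 0.22 (adjusted p = 3.32e-14), Mef2c by 2.36 ± 0.17, Mymk by 2.25 ± 0.22 and Myog by 0.95 ± 0.14 (adjusted p = 1.09e-05). Pax3 fell (-0.61 ± 0.19, adjusted p = 0.0134), while Pax7 had 0.00 ± 0.10 (adjusted p = 0.983). Pax3 lost its call without E16.5 replicates 1 to 4 (adjusted p = 0.0567) or 5 to 8 (0.0950). At the neuromuscular junction 12 of 15 rose and 1 fell, with Musk at 1.86 ± 0.21 (list median 0.53, adjusted p = 2.15e-07, and adjusted p = 0.0768 with an estimated correlation). Of 41 matrix genes 26 rose and 6 fell, among them Postn, periostin (2.62 ± 0.28; list median 0.49, adjusted p = 2.85e-09, and adjusted p = 0.0935 with an estimated correlation). Tendon genes rose in 5 of 15 cases and fell in 3 (median 0.10, and 0.06 without E16.5 replicate 2; adjusted p = 0.00593; adjusted p = 0.0902 with an estimated correlation).

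Among the lists that fell, cell cycle had 47 of 52 genes lower and 0 higher (unadjusted, 48 and 0; median -0.72, adjusted p = 2.22e-17; adjusted p = 0.0600 with an estimated correlation). Fold mesenchyme had 24 of 29 lower and 1 higher (median -1.03, adjusted p = 6.94e-10), hernia genes 25 of 41 lower and 6 higher (median -0.50, adjusted p = 0.000308), and Hox genes 19 of 28 lower and 0 higher (unadjusted, 22 and 0; median -0.48, adjusted p = 3.29e-07), and these 3 calls held with an estimated correlation. Aldh1a2 fell by 2.78 ± 0.35 on the log2 scale, Robo1 by 2.46 ± 0.15 and Wt1 by 1.60 ± 0.13. Retinoic acid genes were lower in 12 of 24 cases and higher in 4, with Nr2f1 at -2.25 ± 0.16 (list median -0.22, adjusted p = 0.0167, and adjusted p = 0.0746 with an estimated correlation). Wnt genes were lower in 19 of 43 cases and higher in 3 (median -0.16, adjusted p = 0.0199; adjusted p = 0.128 with an estimated correlation), and Hedgehog genes lower in 8 of 17 and higher in 0, also unadjusted (median -0.26, adjusted p = 0.0135; adjusted p = 0.147 with an estimated correlation). Without E16.5 replicates 5 to 8 neither passed (adjusted p = 0.102 and 0.0716). The Wnt median was -0.24 without E11.5 replicate 8, and the Hedgehog median -0.16 without E11.5 replicate 2. Imprinted genes rose in 12 of 18 cases and fell in 3 (median 0.37, adjusted p = 0.000278; adjusted p = 0.103 with an estimated correlation). Otor, otoraplin, a secreted protein of the inner ear, fell by 3.61 ± 0.42 on the log2 scale.

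Hepatocyte markers rose in 16 of 19 cases and fell in 0 (unadjusted, 17 and 0; median 3.58, adjusted p = 2.32e-16, and adjusted p = 0.0935 with an estimated correlation). Endothelial genes rose in 10 of 21 and fell in 0 (unadjusted, 12 and 0; median 0.27, adjusted p = 0.000351; adjusted p = 0.248 with an estimated correlation). The list did not pass without E16.5 replicates 1 to 4 (median 0.03, adjusted p = 0.240) and had a median of 0.47 without replicates 5 to 8. Its mean was 7.80 to 8.18 per array at E11.5 and 8.03 to 8.26 in replicates 5 to 8. Of the other markers, macrophage genes rose in 6 of 21 and fell in 1 (median 0.24, and 0.15 without E11.5 replicate 3; adjusted p = 0.00380; adjusted p = 0.134 with an estimated correlation). Cardiomyocyte genes rose in 4 of 13 and fell in 2 (median 0.16, adjusted p = 0.0376; adjusted p = 0.264 with an estimated correlation), a call that ended without E16.5 replicate 8 (median 0.06, adjusted p = 0.0895), E11.5 replicate 4 (0.0589) or E16.5 replicates 5 to 8 together (0.0852). Immediate early and heat shock genes rose in 8 of 22 and fell in 2 (median 0.15, adjusted p = 0.000402; adjusted p = 0.105 with an estimated correlation). The lung list (adjusted p = 0.313) had a median of -0.04 and a mean of 0.26 with the test pointing up, the red blood cell list (adjusted p = 0.583) a median of 0.22 and a mean of -0.98 with the test pointing down (past the threshold without E16.5 replicates 5 to 8, 0.0444), and cartilage and bone (adjusted p = 0.865) a median of -0.02 and a mean of 0.09. Mesothelium (adjusted p = 0.447), neurons (0.160) and Schwann cells (0.904) did not pass. With fry mesothelium (adjusted p = 0.024), neurons (0.0012) and the red blood cell list (0.0012) did pass, and Schwann cells (0.589) did not. With the hepatocyte list's mean per array as a covariate, an alternative chosen after the data were seen, 2282 genes changed instead of 6479, 1943 of them the same genes in the same direction and 18 in the opposite one.

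Over both steps 59 genes changed at each. Of these 45 rose at both, where independent lists would share 7.4, and they include Aspn (2.0, then 3.55 on the log2 scale), Actn2 (2.12, then 3.19), Myoz2, a Z-disc protein (1.93, then 3.80), Mylpf (1.89, then 2.23), Smpx (1.85, then 4.38) and Alb (4.29, then 2.36). Another 9 rose and then fell, where independent lists would share 10.0, among them Rspo3 (1.58, then -0.82), Fst, follistatin, an antagonist of activins and myostatin (0.77, then -0.64), Myc (0.62, then -1.18), Cyp7b1, an enzyme of oxysterol metabolism (0.65, then -0.58), Myod1 (0.74, then -0.52) and Dtymk, thymidylate kinase (0.43, then -0.91). The 5 that fell at both steps were Nr2f1 (-1.01, then -1.23), the protease Casp6 (-0.75, then -1.32), the membrane protein Tenm4 (-0.55, then -0.85), the chromatin remodeller Chd6 (-0.44, then -0.41) and Marf1, an RNA-binding protein (-0.29, then -0.33), where independent lists would share 1.7. None fell and then rose, where independent lists would share 1.3 and limma gave 11 genes lower at the first step in all.

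Since the E12.5 arrays enter both steps with opposite sign, noise alone pulls the changes of the steps apart. The correlation across genes was 0.223, against -0.502 in simulated arrays with no change, and 0.271 when the E12.5 arrays were divided into separate sets of 4 (0.165 to 0.358 over 70 divisions); genes are not independent replicates. The 59 genes became 37, 35 and 37 without E11.5 replicates 5, 7 and 8, and 22, 108, 27, 30, 31 and 29 without E12.5 replicates 1, 2, 3, 4, 6 and 8, and first-step calls ended without 1 array (Fst), any 1 of 2 (Tenm4), 4 (Myc), 7 (Marf1, Myoz2), 9 (Casp6, Cyp7b1), 11 (Myod1), 12 (Dtymk) or 13 (Chd6), at adjusted p up to 0.0950. Without E16.5 replicates 1 to 4, 26 genes changed at both steps and the second step of Rspo3 (adjusted p = 0.102), Fst (0.0731), Cyp7b1 (0.0638) and Chd6 (0.134) did not pass. Without replicates 5 to 8 there were 25, and the second step of Rspo3 (adjusted p = 0.0619) and Myod1 (0.134) did not pass.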

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

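The tests of array scaling on Alb, of Xist, both tests on E12.5 replicate 3, and the look at red cell genes in E12.5 replicate 2 were chosen only after the results were seen. Within each stage, the highest or lowest array was singled out when its gap to the nearest other array exceeded Dixon's critical share of the range of the 8 arrays, which chance alone does in about 1 in 20 groups. Of 399 groups tested 47 did (11.8%): 1 of 3 for the correlation between arrays, 11 of 81 list means and 35 of 315 groups of named genes. E12.5 replicate 3 accounts for 10 of them, E12.5 replicate 2 for 7, E16.5 replicate 8 for 6 and E11.5 replicate 1 for 5; genes that move together are not independent groups.

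Liver transcripts were higher at E16.5 than at E11.5: 16 of 19 hepatocyte markers rose, with a median log2 change of 3.58, and Alb reached 12.81 ± 0.57 (SD, n = 8) at E16.5. The lowest Alb change over 3 scalings was 6.61. Array medians already lay between 7.44 and 7.55, so these scalings could move it little and cannot decide on scaling as a cause. A candidate source is liver cells or their RNA, which laser capture is meant to leave out; of the hepatocyte list 2 genes (Rbp4 and Ttr) are also retinoic acid genes, and how many the diaphragm expresses was not tested. A second list of 31 liver genes, 0 of them on the 27 lists and 29 measured, had a median of 0.49 (quartiles 0.20 to 1.12, 13 higher and 0 lower in limma, unadjusted 16 and 0), just under the 0.5 set beforehand as the bound against this source and short of the 1 that would speak for it. Because the quartiles span both bounds, a condition added once the value was known, the source stays open, as does a change within the diaphragm as it develops, which was not tested.

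E12.5 replicate 2 had the lowest mean correlation with its own stage (0.956, the next array 0.974), the highest hepatocyte mean (11.43, next 9.30) and Fgg (11.60, next 7.92), and the lowest myogenic mean (8.27, next 8.54), Chrnb1 (7.24, next 8.39), Fat3 (10.88, next 11.45) and Myog (9.71, next 10.32). A noisier hybridisation is argued against, since 175 genes lay 4-fold above the median of the other E12.5 arrays and 14 below, a ratio of 0.08. Liver RNA of an older animal may be in this array: of 28 measured genes of an adult liver list, 0 of them on the 27 lists, 18 were higher here than in each of the other 23 arrays, Cyp1a2 with 8.4 against at most 5.93. Xist is consistent with RNA of more than 1 animal, as it had 7.87 here, 1.84 above the highest of the 12 other arrays with Y-linked transcripts, while the 11 arrays without these had at least 11.28 and Eif2s3y was 9.40. The age of the liver stays open, the same stage included, because the median of the adult list here minus the highest E16.5 array was 0.76, between the bounds of 0 and 1, and red cell genes without globins had a mean of 9.26 here (7.53 to 8.15 in the other E12.5 arrays, 11 of 17 genes higher than in each of the other 23), which blood-forming fetal liver would bring and adult liver alone would not; the design gives no biological explanation to test.

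E12.5 replicate 3 was the highest of its stage in the mean of muscle energy metabolism (9.37, next 8.43) and in Atp1b4 (10.68, next 6.32), Casq1 (10.94, next 8.08), Ckmt2 (8.58, next 6.27), Cmya5 (8.44, next 7.17), Dpt (9.84, next 6.03), Lama2 (8.76, next 8.4), Myf6 (7.78, next 6.42), Myh8 (12.34, next 9.26) and Ppp1r3a (7.91, next 6.11). RNA of E16.5 diaphragm may be in this array: over 75 muscle genes a median of 20.8% of the rise to E16.5 was present (quartiles 11.51% to 30.4%) and over 11 matrix and tendon genes 19.9% (7.20% to 22.6%), a ratio of 0.956. The share was 8.01% (7.56% to 21.1%) over 5 oxidative phosphorylation genes and 19.2% over 2 endothelial genes. Over 16 hepatocyte markers it was 2.21% (-2.18% to 4.90%). This keeps RNA of E16.5 diaphragm open as a source, since E16.5 tissue low in liver transcripts could have given it. The lowest hepatocyte mean at E16.5 was 8.85, in replicate 4. That sample itself is not a likely source, as its Xist was 11.28, against 5.43 in E12.5 replicate 3. A larger muscle share at the same stage is open too, because 5 early muscle genes lay a median of 0.39 above the other E12.5 arrays (Msc 0.04 to Mymk 0.89), between the bounds of 0.2 and 0.7. The design gives no biological explanation for a single array, and none was tested.

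E11.5 replicate 1 was the highest of its stage in the sarcomere mean (8.98, next 8.47), Actn2 (8.86, next 7.69), Hrc (9.88, next 8.22), Meox1 (10.77, next 9.92) and Trdn (7.58, next 6.51). Replicate 2 of that stage had the highest Schwann cell mean (7.60, next 7.29), and replicate 3 the highest Afp (7.66, next 6.83) and Cmya5 (7.30, next 6.92). In E11.5 replicate 4 the cardiomyocyte mean was lowest (7.06, next 7.23), as was Ppp1r3a (5.04, next 5.39), and the tendon mean highest (7.72, next 7.59). Dpt was highest in E11.5 replicate 5 (7.32, next 5.93), and in replicate 7 the neuronal mean was highest (7.54, next 7.25) and Postn lowest (7.93, next 9.46). At E12.5, replicate 4 had the lowest Aldh1a2 (7.62, next 10.16) and Tmtc2 (9.10, next 9.60), and replicate 5 the highest cardiomyocyte mean (7.92, next 7.41).

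At E16.5, replicate 1 had the highest Myod1 (9.40, next 8.91). Replicate 4 had the lowest Alb (11.53, next 12.54) and Pax7 (7.35, next 7.61) and the highest Nefm (7.77, next 6.52). Rimklb was highest in replicate 5 (7.43, next 6.37), and Crabp2 (9.52, next 8.47) and Col3a1 (10.55, next 10.32) in replicate 6. E16.5 replicate 8 had the highest cardiomyocyte mean (8.42, next 7.88) and Myc (9.58, next 8.86), and the lowest Hox mean (7.21, next 7.34), Aspn (11.31, next 11.84), Cox8b (12.14, next 12.65) and Dpt (10.96, next 11.53).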

How the results depend on the processing

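The fit with the hepatocyte mean as a covariate and those without E12.5 replicates 2 and 3 or without 4 E16.5 arrays were chosen only after the results were seen. Causes of the shifts below were not tested, except that leaving out arrays or genes leaves fewer to test and treat asks for a larger change. For E12.5 with E11.5, 75 genes (64 higher, 11 lower) became 9 (8 and 1) with only those stages in the fit, 4 (4 and 0; unadjusted 60, of which 2 lower) with treat, and 0 (0 and 0; unadjusted 2502) in the unmoderated unequal-variance test. Array weights gave 120 (99 and 21). Replicate number as a block gave 43 (41 and 2; 39 of them shared), although equal numbers showed no pairing: deviations of same-numbered arrays correlated at -0.281 to 0.0927. Quantile normalization gave 49, of which 39 higher; centring on the 75th percentile left 33 higher and 31 lower, and on the median 31 lower. The count of lower genes was 6 without the dimmest 50% of genes, 17 with trend and robust options and 7 without E12.5 replicates 2 and 3. The count was 32 (28 and 4) without E16.5 replicates 1 to 4 and 34 (31 and 3) without replicates 5 to 8. Leaving out each array gave 26 (without E12.5 replicate 1) to 151 (without E12.5 replicate 2) genes, 24 to 131 higher and 1 (without E11.5 replicate 7) to 54 (without E11.5 replicate 4) lower. The 59 genes changed at both steps became 8 with only the stages compared, 38 with the block, 91 with array weights, 0 in the unequal-variance test, 26 and 25 without E16.5 replicates 1 to 4 and 5 to 8, and 22 to 108 without single arrays.

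The later comparisons moved less. For E16.5 with E12.5 treat gave 803 genes (545 higher, 258 lower), and for E16.5 with E11.5 1064 (753 and 311). With the hepatocyte covariate the latter had 2282 (1201 and 1081); since that mean rises with stage, the covariate takes up part of the stage difference too. Without E16.5 replicates 1 to 4 the counts were 3479 (1945 lower) and 4265 (2297 lower), of which 3227 and 4023 were shared. Leaving out each array gave 4876 to 5328 and 6018 to 7163 genes. Centring on the 75th percentile took the median of all genes from -0.03 to -0.10 in E12.5 with E11.5, from -0.02 to 0.03 in E16.5 with E12.5, where its sign turned, and from -0.08 to -0.10 in E16.5 with E11.5. Without the dimmest 50% of genes the first turned too (0.04) and the second was -0.09. Of 53 list tests past the threshold 16 were with an estimated correlation, and 51 to 56 without single arrays. With fry, the myogenic, calcium handling, junction, energy metabolism, oxidative phosphorylation and matrix lists did not pass in E12.5 with E11.5 (adjusted p = 0.0719 to 0.198). Red blood cells (adjusted p = 0.000425) and lung epithelium (0.024) passed with fry and not with camera in E16.5 with E12.5. In E16.5 with E11.5 mesothelium, neurons and red blood cells did. The first component held 70.6% of variance over the 1000 most variable genes.

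With the hepatocyte covariate 3 values reversed: Rbp4 in E16.5 with E12.5 (-0.46, adjusted p = 0.146; 0.00107 to 0.248 over its alternatives), and in E12.5 with E11.5 the erythroid list (median -0.31, adjusted p = 0.00297; up to 0.849) and the hepatocyte list (-0.32, adjusted p = 0.716; down to 4.79e-26). The covariate is the hepatocyte list's own mean, which holds Rbp4, so for that list and Rbp4 it removes the change by construction and tests nothing. Over 155 named gene values and all settings but treat, 5692 of 6035 pairs kept direction and side of the threshold, 328 no longer passed, 14 newly passed and 1 reversed. Of the changed genes given by the naming rule for each comparison, 14 of 23, 135 of 147 and 145 of 151 kept their call with each array left out. These counts leave aside genes named only for their class over both steps. Among the 28 changed genes named in E12.5 with E11.5, which include such genes, 14 kept theirs.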

Other observations

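The gene families below, and the test of scaling on Hbb-bh1, were chosen only after the results were seen. From 24 families picked by gene symbol, 72 tests were made with camera and adjusted among themselves. Of these 27 passed, and 4 with an estimated correlation. RNA-binding hnRNP and SR proteins, which act in splicing, fell from E12.5 to E16.5 in 24 of 27 cases and rose in 0 in limma (unadjusted, 24 and 0; median log2 change -0.43, adjusted p = 1.96e-12, and adjusted p = 0.0370 with an estimated correlation). Among them were Srsf9 (-0.76 ± 0.15), Hnrnpr (-0.73 ± 0.12) and Hnrnpl (-0.66 ± 0.08). Eph receptors and ephrins, contact signals between cells, fell in 11 of 20 cases and rose in 0 (unadjusted, 12 and 1; median -0.38, adjusted p = 0.000210, and adjusted p = 0.00696 with an estimated correlation), among them Epha7 (-1.64 ± 0.24), Epha4 (-1.49 ± 0.22), Epha3 (-1.35 ± 0.21) and Efna5 (-1.30 ± 0.26).

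Histones fell in 16 of 35 cases and rose in 2 (median -0.29, adjusted p = 0.000578; adjusted p = 0.145 with an estimated correlation), with H2ax at -1.01 ± 0.11. Mitochondrial ribosomal proteins rose in 20 of 77 cases and fell in 2 (median 0.18, adjusted p = 0.000210; adjusted p = 0.359 with an estimated correlation), with Mrps36 at 1.24 ± 0.16. Between E11.5 and E12.5 the 30 aminoacyl-tRNA synthetases were higher as a set, with 0 single genes past limma's threshold (unadjusted, 6 higher and 0 lower; median 0.17, adjusted p = 2.22e-05, and adjusted p = 0.0129 with an estimated correlation). The median was 0.12 after quantile normalization and 0.10 with arrays centred on the 75th percentile.

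The fall of the embryonic globins raised the hypothesis that red blood cells were fewer in the E16.5 captures. It would lower other red cell transcripts too: 18 such genes without globins, 0 of them on the 27 lists, were listed and 17 measured. Over the 14 of these brighter at E12.5 than the median gene, the median log2 change was 0.11 (-0.15 to 0.72). In limma 0 were lower and 1 higher past the threshold (unadjusted, 0 and 2). A fall of 2 or more had been set as the mark. Genes with E12.5 means of 7.60 (Sptb) to 9.60 (Slc25a37) could not all show it above the lower quartile. The values argue against fewer red cell transcripts in these captures as a whole. Whether red cell transcripts from liver masked a loss of red cells cannot be told. The change of Hbb-bh1 nearest to 0 over 3 scalings was -5.62. Array medians already lay between 7.44 and 7.55, so these scalings could move it little and cannot decide on scaling as a cause. A change in which globins red cells make at these stages stays open, as do red cell transcripts from liver at E16.5, and neither was tested.

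The counts were set against other divisions of the arrays into groups of the same sizes, 100 per result with the real stages included. In each, 1 division, the real one, gave as large a count, which excludes chance only if the arrays are independent. Arrays that share an embryo, or the 2 sets among the E16.5 arrays, are not covered by this. The real counts and the highest of the other divisions were 75 and 2 genes for E12.5 with E11.5, 5241 and 2179 for E16.5 with E12.5, 6479 and 3897 for E16.5 with E11.5, and 59 and 0 for genes changed at both steps. In the later comparisons, divisions that kept 7 of the 8 arrays of a stage together gave 1748 to 2179 and 3897 genes, and those that kept 4 or 5 together at most 2, so the high counts point to the structure that the stages give the arrays. For the list tests the real count was 53 and the highest other 48. The other divisions gave 3 to 48 list tests past the threshold, with a median of 27, so camera with the preset correlation calls many lists even where groups mix the stages.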
